A study of Homo sapiens with 6 samples.

How the data were processed

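Total RNA from SUM159 cells, an established human triple-negative breast carcinoma line, was measured on 6 single-colour gene expression arrays. Per the labels, 3 samples were from cells given 1 µM decitabine for 72 h with daily changes of medium, and 3 were from cells in control medium for 72 h, which are called untreated here. The labels do not say whether the control medium held the drug's solvent, and the titles of the control samples carry the 1 µM dose too, which was not taken as a treatment. The treatment protocol names the drug as a deoxy form of azacytidine, whereas the sample descriptions and the series design name decitabine, and the latter name is used. Per the labels' protocols, RNA was collected in Trizol, purified on a column kit and labelled with biotin. Groups were taken from the treatment label and replicate numbers from the sample titles.

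The deposited table held 48226 array features for each of the 6 samples. The values had been made by the authors with the Transcriptome Analysis Console, per the submitters' processing notes; its version, the normalization, the filters and the genome build are not given in the sources used here. The deposited values were read as log2 expression values, because they ran from 0.17 to 12.89 with 2 decimals as log2 array summaries do. The log base itself is not stated, so each log2 change and fold below rests on that reading. The arrays had not been brought to a common distribution: medians over all features were 3.03 and 2.98 in untreated and decitabine replicate 1, and 2.29 to 2.42 in the other arrays. No further normalization or intensity filter was applied before the main test. No measure of signal over background was used, so changes from or to dim levels are those of the deposited values, and the number of arrays limits the precision.

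Features were named through the platform annotation, and symbols were updated by Entrez Gene ID through a RefSeq gene table of GRCh38.p14. Of the 48226 features, 16098 carried a single gene symbol, none carried several, and 32128 were without a name here. All 16098 Entrez Gene IDs matched the RefSeq table. They gave 14884 genes, 779 of which had more than 1 feature, and the feature with the highest mean over the 6 arrays stood for its gene. No genome build was named for the arrays, so no coordinates are given, and the RefSeq table supplied symbols, gene types and chromosomes only. Genes and list members without a named feature were not analysed here.

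The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 6 arrays in the fit and no covariate. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 14884 genes, and genes with an adjusted p under 0.05 are said to have risen or fallen. Changes are decitabine minus untreated with the standard error (SE) from the fit. Nothing in the labels says that the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. The moderated fit was tested on simulated data for this comparison, with 100 of the 14884 genes changed 2-fold and 100 changed 4-fold. It recovered 0% of genes changed 2-fold and 55% of genes changed 4-fold, with 0 false calls. With the replicate number as a block it recovered 37% and 78%, again with 0 false calls. The simulated fit without a block called 55 genes, against 451 in the data, where the adjusted threshold was easier to reach. The smallest change past it in the data was 0.89 on the log2 scale, so these shares are not the power of the real comparison. In the same simulation a list of 30 genes shifted by 1 on the log2 scale gave p = 2.52e-84 with the preset correlation and 2.42e-05 with an estimated one, and an unshifted list gave 0.584 and 0.837. The genes of these lists were drawn at random, so the simulation does not cover lists whose members vary together.

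The groups share replicate numbers in the sample titles, and whether these pair the samples was checked before the fits were compared. The deviations from the group means, over all genes, correlated at 0.682, 0.595 and 0.558 between arrays with the same number, and at -0.006 to -0.483 between arrays with different numbers. Same-numbered arrays also held identical values at 6.44%, 7.94% and 8.28% of features, against 0.42% to 1.02% for the other pairs of arrays. The numbers were therefore taken to pair the samples, on the titles and this check. The check cannot tell samples handled together in the experiment from arrays processed together afterwards. The fit without a block, chosen before the data were examined, remained the main one. Values with the replicate number as a block are given beside a result where they change a call or move a count by more than 1.5 times.

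Before the data were examined, 31 gene lists were fixed, 24 of pathways and gene families and 7 of markers of other cell types. The 29 lists with at least 3 measured members were compared with the other genes by camera (limma) with a preset correlation of 0.01, adjusted over the 29 lists. The lists of multidrug efflux transporters and of replication-dependent histones had no member with a named feature and were not analysed here. Camera was repeated with a correlation estimated for each list, which is a stricter test, and not only when members vary together. The estimates for the ATF4 and unfolded protein list (0.0129) and for decitabine handling (-0.0223) were near or below the preset 0.01. Their p-values still became larger. A larger p-value with an estimated correlation is therefore not by itself a sign that members vary together. Fry (limma) tested whether the members of a list moved, on balance, in a single direction or changed in either direction, without comparing them with other genes. Counts of changed members are given after adjustment over all genes and after adjustment over the list alone. The share of genes on the X chromosome was compared by a two-sided Fisher's exact test, with 95% confidence intervals for the odds ratio.

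Genes were named by a rule fixed before the data were examined. It took the 5 largest rises and the 5 largest falls among genes past the threshold whose groups did not overlap, leaving out pseudogenes and uncharacterised loci. It added 12 genes of decitabine action and drug handling, of which 7 had a named feature, and the 3 most changed members past the threshold of each main list, or 2 of each further list. Where no member passed, the most changed member is given by value. Where a list had 5 or fewer changed members, those outside the rule are also named, and these were chosen after their values were seen. The same holds for the members of lists in the closing section that were drawn up after the data were examined.

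The alternatives were the replicate block, quantile normalization, median centring of each array, leaving out the dimmest 25% or 50% of genes, averaging all features of a gene, an intensity trend with robust variance estimation, array quality weights, testing every feature, and leaving out each array in turn. Added after the data were examined were leaving out both arrays of replicate 1, the block together with quantile normalization or with estimated correlations, and the X-chromosome share under the block. Fits with a single array left out had no block, so they also left its same-numbered partner unpaired. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.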

Results

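Gene expression was measured in SUM159 cells after 72 h in 1 µM decitabine and in untreated cells, with 3 arrays per group. SUM159 is a triple-negative breast carcinoma line, and decitabine is a deoxycytidine analogue that is built into DNA and traps DNA methyltransferases there. The comparison asks which genes change expression after exposure to the drug. Pearson correlations over all 48226 features were 0.9596 to 0.9775 within a group, 0.9648 to 0.9702 between arrays of the same replicate number in different groups, and 0.9455 to 0.9599 between the other arrays. The first principal component (41.58% of the variance) placed both arrays of replicate 1 apart from the others, and the second (35.09%) parted the groups. Both arrays of replicate 1 also had the higher medians over all features, 3.03 and 2.98 on the log2 scale against 2.29 to 2.42.

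**Figure D1:**
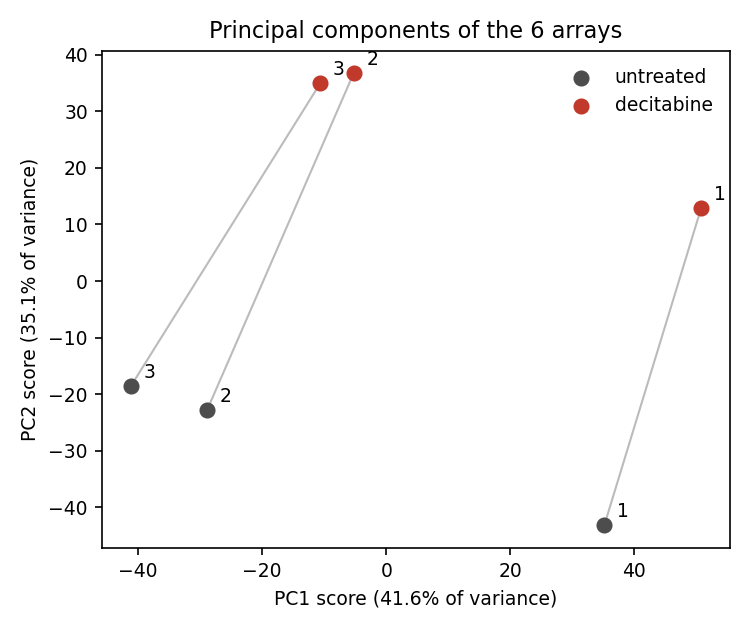
Principal component analysis of the 6 arrays over 14884 genes, with component 1 (41.58% of the variance) on the horizontal axis and component 2 (35.09%) on the vertical axis, both in units of the component score, each point an array labelled by its replicate number and coloured by group, and grey lines joining arrays of the same number. The decitabine arrays lie between 12.92 and 36.7 on component 2 and the untreated arrays between -43.2 and -18.6, and on component 1 the arrays of replicate 1 lie at 35.1 and 50.8 and the other arrays below 0.

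Genes of meiosis and of germ cells were among the largest rises after decitabine, and genes of amino acid synthesis and the integrated stress response were among the largest falls. SYCP3 (Entrez Gene 50511), a component of the synaptonemal complex that joins chromosomes in meiosis, rose from 1.72 ± 0.32 to 7.88 ± 0.42 (SD, n = 3 per group), a log2 change of 6.16 (SE 0.28), with a limma adjusted p of 6.66e-05. TKTL1 (8277), a transketolase-like protein, rose by 5.61 (SE 0.33), and HORMAD1 (84072), a protein of the meiotic chromosome axis, by 5.45 (SE 0.34). STOM (2040), the membrane protein stomatin, rose by 5.18 (SE 0.24), and MAEL (84944), a factor of the piRNA pathway that silences transposons in germ cells, by 4.88 (SE 0.31). Adjusted p-values of these 4 genes were 6.66e-05 to 3.07e-04. All 5 had untreated means of 1.59 to 2.69, near or below the untreated array medians of 2.29 to 3.03. No measure of background was used, so the sizes and order of rises from such dim levels hold only for the deposited values.

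The largest falls were led by ASNS (440), asparagine synthetase, which went from 8.73 ± 0.12 to 5.11 ± 0.11 (SD, n = 3 per group), a log2 change of -3.62 (SE 0.19), or 12.3-fold, with a limma adjusted p of 1.64e-04. DDIT4 (54541), a stress-induced inhibitor of mTORC1, changed by -3.28 (SE 0.30), and UNC5B (219699), a netrin receptor, by -3.05 (SE 0.38). CTH (1491), the cystathionine gamma-lyase that forms cysteine, changed by -2.93 (SE 0.21), and the long noncoding RNA LINC00632 (286411) by -2.81 (SE 0.36). Adjusted p-values of these 4 genes were 4.86e-04 to 0.00699. The 10 genes kept their call when any single array was left out.

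**Figure D2:**
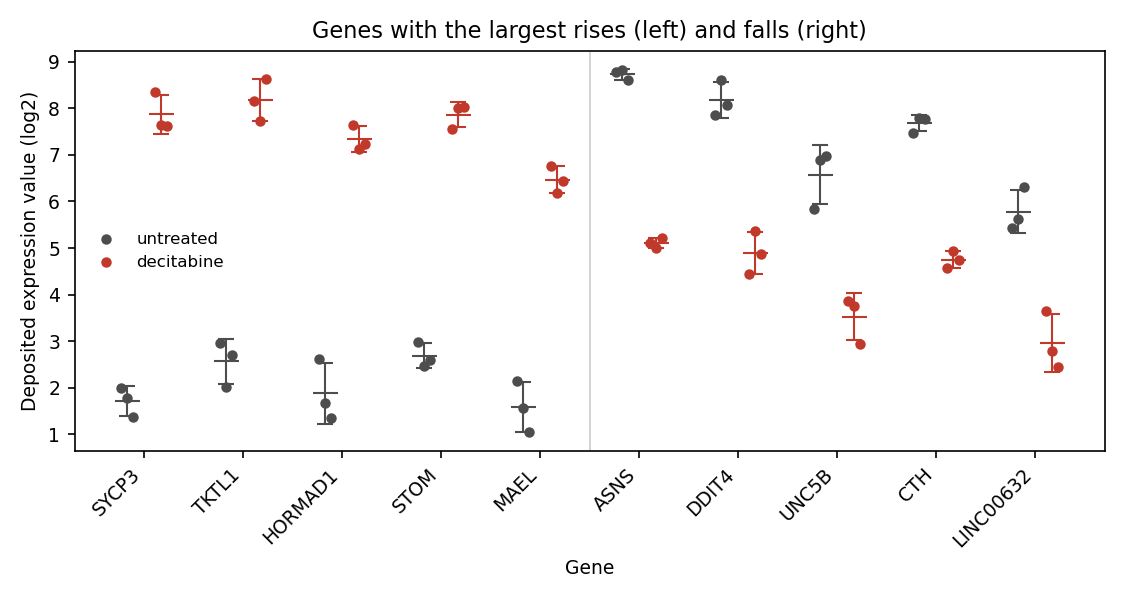
Expression of the 5 genes with the largest rises (left) and the 5 with the largest falls (right), with genes on the horizontal axis and the deposited log2 expression value on the vertical axis; each point is an array, grey for untreated and red for decitabine, with horizontal lines at the group means and bars of 1 SD (n = 3). The groups do not overlap for any of the 10 genes, as for SYCP3 with means of 1.72 and 7.88 and ASNS with means of 8.73 and 5.11.

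In all, 299 genes rose and 152 fell after decitabine, and 432 of these 451 genes changed at least 2-fold, 290 upward and 142 downward. The 3 decitabine values of each of the 451 genes lay on a single side of the 3 untreated values, so each gene necessarily moved in a single direction in all 3 same-numbered pairs. Groups were separated in this way for 2986 of the 14884 genes. Chance gives 10% for exchangeable arrays, which paired arrays are not, so that share is only a rough yardstick. Of the genes that rose, 273 were protein-coding, 15 were long noncoding RNAs and 7 were transcribed pseudogenes, and of those that fell, 138 were protein-coding, 10 were long noncoding RNAs and 4 were microRNAs. With the replicate number as a block, 1159 genes rose and 800 fell, among them all 451, and 702 of the 1959 changed at least 2-fold. Counts were 107 and 33 without untreated replicate 2, 135 and 53 without untreated replicate 3, 180 and 98 without decitabine replicate 1, 95 and 35 without decitabine replicate 2, 152 and 47 without decitabine replicate 3, and 321 and 156 without untreated replicate 1. With both arrays of replicate 1, the arrays of higher median, left out, 245 genes rose and 143 fell.

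Of 42 measured genes of meiosis and germ cells 14 rose and none fell, 28 did not pass the test, 15 rose when adjusted over the list alone, and the median change was 0.39 on the log2 scale (0.31, 0.47 and 0.37 in the 3 pairs). Besides SYCP3, HORMAD1 and MAEL, the 14 included the synaptonemal complex gene SYCP2 and the piRNA pathway genes TDRD1, TDRD9, TDRD12, PIWIL2 and PIWIL4, named after their values were seen, with changes of 2.24 (PIWIL4) to 4.26 (TDRD1). The list lay above the other genes by camera (adjusted p = 8.82e-11), but the adjusted p was 0.463 with an estimated correlation.

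Cancer-testis antigens are normally restricted to germ cells and are expressed in some tumours. Of the 75 in the list, 20 were measured, of which 4 rose and none fell. Their median change was 0.37 (0.30, 0.19 and 0.56 in the pairs). No listed gene of the MAGE, SSX or SPANX families had a named feature, so these were not analysed here. TKTL1 rose by 5.61, LUZP4, an mRNA export factor, by 2.25 (SE 0.26, adjusted p = 0.00503), and DDX53, an RNA helicase, by 2.23 (SE 0.25, adjusted p = 0.00394). The fourth was CTCFL, the germ-cell paralogue of CTCF, which rose by 1.08 (SE 0.21, adjusted p = 0.0335). Adjusted over the list alone 8 rose, and 8 rose with the replicate block. The camera adjusted p was 9.28e-06, and 0.505 with an estimated correlation. The list holds families of near-identical copies, such as the GAGE genes, whose array features cannot part the copies, so values of those members are uncertain.

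Of 29 measured genes of DNA replication and S phase, 18 rose and none fell, 11 did not pass the test, and 25 rose when adjusted over the list alone. The median change was 1.34 (1.00, 1.23 and 1.51 in the pairs), and the camera adjusted p was 3.79e-31, or 0.128 with an estimated correlation. CCNE2, a cyclin of the entry into S phase, rose by 2.56 (SE 0.22, adjusted p = 0.00145), and E2F8, a transcription factor of the E2F family, by 2.35 (SE 0.23, adjusted p = 0.00234). The list of G2, M phase and mitosis genes had a smaller median change of 0.37 (0.50, 0.30 and 0.36 in the pairs), with 3 of 48 members higher and none lower. KIF20A, a mitotic kinesin, rose by 1.68 (SE 0.20, adjusted p = 0.00509), CDC25A, a phosphatase that activates cyclin-dependent kinases, by 1.49 (SE 0.26, adjusted p = 0.0250), and CDK1 by 1.18 (SE 0.19, adjusted p = 0.0181). Its camera adjusted p was 4.08e-09, or 0.320 with an estimated correlation, 6 members rose over the list alone, and 16 rose with the replicate block. CDC25A missed the threshold without untreated replicate 2, decitabine replicate 2 or decitabine replicate 3 (adjusted p of 0.103 to 0.122), and with median centring (0.0983).

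Of 16 measured ATF4 targets and unfolded protein response genes, 11 fell and none rose, with a median change of -1.79 (-1.66, -1.85 and -2.14 in the pairs), a camera adjusted p of 2.08e-13 and an adjusted p of 0.0476 with an estimated correlation. Adjusted over the list alone 11 fell and 1 rose, and with the replicate block 11 fell and 1 rose. The transcription factor ATF4 itself changed by -1.20, and members that act in amino acid synthesis (ASNS, CTH, PHGDH, PSAT1) changed by -3.62 to -1.88. The members TRIB3, DDIT3, ERN1 and XBP1, which encode a pseudokinase, a transcription factor, and the sensor and effector of an arm of the unfolded protein response, changed by -2.47 to -1.57. The 8 members ATF4, PHGDH, PSAT1, TRIB3, DDIT3, ERN1, XBP1 and SDF2L1 are named after their values were seen. SDF2L1, an endoplasmic reticulum chaperone component, changed by 0.72 and passed only over the list alone and under the block. With the block and an estimated correlation together, an added setting, the adjusted p of the list was 0.434.

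Targets of p53 did not differ from the other genes as a list (median -0.02, camera adjusted p = 0.325), with no rise and 3 falls among 20 measured members. SESN2, a stress-induced protein that is also in the ATF4 list, changed by -2.74 (SE 0.29, adjusted p = 0.00333), GDF15, a stress-induced cytokine, by -1.52 (SE 0.28, adjusted p = 0.0281), and SUSD6 by -1.24 (SE 0.23, adjusted p = 0.0326). Adjusted over the list alone, 1 rose and 5 fell, and with the replicate block 3 rose and 5 fell. GDF15 missed the threshold without untreated replicate 1, 2 or 3 or decitabine replicate 2 or 3 (adjusted p of 0.0509 to 0.111). Of 21 apoptosis regulators, BCL2L11, which encodes the pro-apoptotic protein BIM, rose by 1.45 (SE 0.26, adjusted p = 0.0270) and none fell. The list had a median of -0.19 and a camera adjusted p of 0.244, with 2 higher and 3 lower over the list alone and 3 higher and 5 lower with the block. BCL2L11 missed the threshold without untreated replicate 2 or 3 or decitabine replicate 1 or 2 (adjusted p of 0.0779 to 0.129).

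Among 39 measured interferon-stimulated genes 2 rose and none fell, with a median change of 0.34 (0.30, 0.31 and 0.38 in the pairs) and a camera adjusted p of 0.00389, or 0.463 with an estimated correlation. HERC5, the ligase that attaches the ubiquitin-like ISG15 to proteins, rose by 3.11 (SE 0.25, adjusted p = 0.00111), and IFI44 by 1.15 (SE 0.20, adjusted p = 0.0227). When adjusted over the list alone, 5 rose and 1 fell, and with the replicate block 8 rose and 1 fell. IFI44 missed the threshold without untreated replicate 2 or 3 or any of the 3 decitabine arrays (adjusted p of 0.055 to 0.127), and with quantile normalization (0.0603) or median centring (0.12). With the dimmer 50% of genes left out the interferon list had an adjusted p of 0.145.

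Genes of innate nucleic acid sensing and interferon signalling did not differ as a list (15 measured, median 0.11, camera adjusted p = 0.943). The interferon genes of that list had no named feature and were not analysed here. TRIM25, a ubiquitin ligase of the RIG-I pathway, fell by 1.24 on the log2 scale (SE 0.24, adjusted p = 0.0349). It was the single member past the threshold, also over the list alone, while 3 rose and 2 fell with the block. TRIM25 missed the threshold without untreated replicate 2 or 3 or any of the 3 decitabine arrays (adjusted p of 0.0900 to 0.157), and with median centring (0.105). Of the 22 genes in the list of MHC class I presentation, 7 had a named feature, and no HLA gene, TAP1 or TAP2 was among them. None of the 7 passed the test over all genes, over the list alone or with the block. The most changed was CALR, a chaperone of peptide loading, at 0.35 (SE 0.19, adjusted p = 0.527). The median of that list was -0.01, while its mean of 0.06 and camera pointed upward (adjusted p = 0.744). None of 6 measured genes of endogenous retroviral origin passed the test (median 0.09, camera adjusted p = 0.499). PEG10, an imprinted gene derived from a retrotransposon, had the largest change among them, 0.57 (SE 0.19, adjusted p = 0.187, and 0.0346 with the block).

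Among the DNA methylation genes fixed in advance, DNMT3B and UHRF1 were higher after decitabine. DNMT3B (1789), a de novo DNA methyltransferase, rose from 3.03 ± 0.03 to 4.76 ± 0.06 (SD, n = 3 per group), a log2 change of 1.73 (SE 0.18, limma adjusted p = 0.00333). UHRF1 (29128), which brings DNMT1 to hemimethylated DNA, rose by 1.59 (SE 0.26, adjusted p = 0.0179). The change of the maintenance methyltransferase DNMT1 (1786) was 0.49 (SE 0.25, adjusted p = 0.477) and that of DNMT3A (1788) was 0.11 (SE 0.24, adjusted p = 0.993). UHRF1 missed the threshold without untreated replicate 2 or 3 or decitabine replicate 2 or 3 (adjusted p of 0.0669 to 0.0928). Of 14 measured genes of the methylation machinery these 2 rose and none fell, also over the list alone, and 3 rose and 1 fell with the block. The list median was -0.07, while its mean of 0.20 and camera pointed upward (adjusted p = 0.648).

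Among 13 measured genes of decitabine handling and nucleotide metabolism 3 rose and none fell. The median change was 0.39 (0.39, 0.48 and 0.45 in the pairs) and the camera adjusted p was 0.00579, or 0.278 with an estimated correlation. RRM1, RRM2 and TYMS are in the replication list too, so the results of these lists are not independent. No uptake transporter of this list had a named feature. CDA (978), the deaminase that inactivates decitabine, rose by 2.53 (SE 0.23, adjusted p = 0.00171), SAMHD1 (25939), a hydrolase of deoxynucleotide triphosphates, by 1.80 (SE 0.23, adjusted p = 0.00679), and TYMS, thymidylate synthase, which is also in the replication list, by 1.59 (SE 0.30, adjusted p = 0.0335). DCK (1633), the kinase that activates decitabine, changed by 0.57 (SE 0.24, adjusted p = 0.350, and 0.0375 with the block). With p adjusted over the list alone 4 rose and 1 fell, and with the block 6 rose and 1 fell. TYMS missed the threshold without untreated replicate 2 or 3 or any of the 3 decitabine arrays (adjusted p of 0.0613 to 0.15), and the list did so without untreated replicate 1 (0.0539) and with the dimmer 50% of genes left out (0.0536).

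Genes of cholesterol synthesis had 4 of 16 measured members higher and none lower, a median change of 0.48 (0.24, 0.46 and 0.88 in the pairs) and a camera adjusted p of 6.91e-04, or 0.438 with an estimated correlation. HMGCS1, which forms HMG-CoA, rose by 1.84 (SE 0.25, adjusted p = 0.00892), MSMO1, a sterol methyl oxidase, by 1.54 (SE 0.26, adjusted p = 0.0226), IDI1 by 1.46 and NSDHL by 1.33. Adjusted over the list alone, 6 rose. HMGCS1 missed the threshold without untreated or decitabine replicate 2 (adjusted p of 0.0502 to 0.0518), and MSMO1 without untreated or decitabine replicate 2 or 3 (0.0814 to 0.112).

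Epithelial markers had 3 of 28 measured members higher and none lower, a median change of 0.15 (0.14, 0.06 and 0.29 in the pairs) and a camera adjusted p of 0.00906, or 0.584 with an estimated correlation. MARVELD2, the tight junction protein tricellulin, rose by 1.91 (SE 0.27, adjusted p = 0.0103), the basal keratin KRT5 by 1.75 (SE 0.37, adjusted p = 0.0497) and ESRP2, a splicing regulator, by 1.33. When adjusted over the list alone, 5 rose, and with the block 9 rose. MARVELD2 missed the threshold without decitabine replicate 2 (adjusted p = 0.0611), and KRT5 without untreated or decitabine replicate 2 or 3 (0.130 to 0.197) and with median centring (0.0511). With the dimmer 50% of genes left out the list had an adjusted p of 0.182. Mesenchymal markers did not pass as a list (20 measured, median 0.36, camera adjusted p = 0.0856), with 3 higher and 1 lower over all genes and over the list alone, and 8 higher and 3 lower with the block. CCN2, a matricellular protein, rose by 1.84 (SE 0.25, adjusted p = 0.00945), LOX by 1.22 and THBS1 by 1.13, and the receptor tyrosine kinase AXL changed by -1.79 (SE 0.19, adjusted p = 0.00361). The other feature of CCN2 gave 1.65. CCN2 missed the threshold without untreated or decitabine replicate 2 (adjusted p of 0.0545 to 0.0585). The mesenchymal list had an adjusted p of 0.505 with an estimated correlation, 0.0338 with median centring and 0.0192 with both arrays of replicate 1 left out.

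Inflammatory cytokines and NF-κB genes went both ways and did not differ as a list (26 measured, median -0.30, camera adjusted p = 0.260). The chemokines CXCL5, CCL20 and CXCL16 rose by 3.80 (SE 0.31, adjusted p = 0.00112), 2.58 (SE 0.40, adjusted p = 0.0155) and 1.70, and NFKB1, an NF-κB subunit, changed by -1.12. With p adjusted over the list alone 3 rose and 5 fell, and with the block 3 rose and 9 fell. CCL20 missed the threshold without untreated replicate 2 or decitabine replicate 2 or 3 (adjusted p of 0.0506 to 0.0741).

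Tumour suppressors known to be silenced by promoter methylation in cancers did not differ from the other genes as a list (42 measured, median 0.08, camera adjusted p = 0.298). Among them 5 rose and none fell: DKK1, a Wnt antagonist, by 3.63 (SE 0.58, adjusted p = 0.0165), UCHL1, a ubiquitin hydrolase, by 2.78 (SE 0.31, adjusted p = 0.00435), SFN by 1.52, THBS1 by 1.13 and TP73 by 1.01. Adjusted over the list alone, 7 rose and 1 fell, and with the block 7 rose and 4 fell. DKK1 missed the threshold without untreated replicate 3 or decitabine replicate 2 or 3 (adjusted p of 0.0545 to 0.0702). Of 24 measured imprinted genes 3 rose and none fell (median 0.06, camera adjusted p = 0.168), NNAT, neuronatin, by 3.18 (SE 0.32, adjusted p = 0.00276), INPP5F, a phosphoinositide phosphatase, by 1.09 (SE 0.21, adjusted p = 0.0339) and TP73, which is in both lists. When adjusted over the list alone, 3 rose and 1 fell, and with the block 5 rose and 1 fell. INPP5F missed the threshold whichever single array was left out (adjusted p of 0.0656 to 0.164), and with median centring (0.174). These fits had no block. On all 6 arrays its changes were 1.18, 1.08 and 1.00 in the pairs, with a limma adjusted p of 0.00539 with the block.

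Among 11 measured genes of retinoid metabolism, RDH10, a retinol dehydrogenase, rose by 2.36 (SE 0.27, adjusted p = 0.00461), alone over all genes and over the list alone, and the list had a median of 0.03 and a camera adjusted p of 0.926. None of 16 measured clustered protocadherins passed the test in any of these counts (median -0.19, camera adjusted p = 0.325), and the most changed, PCDHB10, was at -0.62 (SE 0.27, adjusted p = 0.351). None of 31 measured ribosomal protein genes passed over all genes or over the list alone. Their median was -0.18, with a camera adjusted p of 0.0542, or 0.0339 with the block and 0.320 with an estimated correlation, and RPL10A was at -0.77 (SE 0.19, adjusted p = 0.0820, or 0.0170 with the block). Left out singly, untreated replicate 1, decitabine replicate 2 and decitabine replicate 3 gave that list adjusted p-values of 0.00852, 0.0188 and 0.0243.

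**Figure D3:**
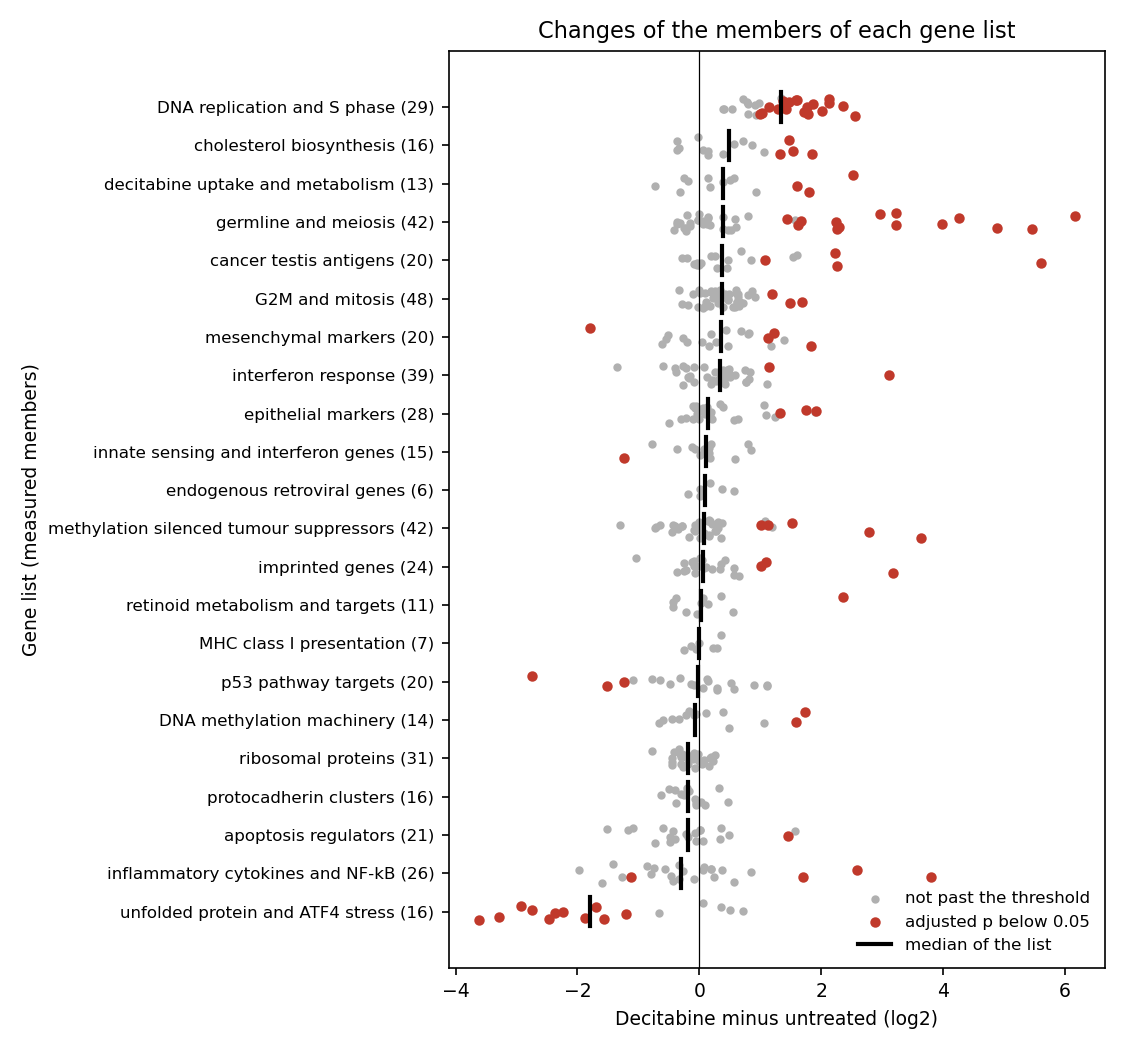
Change of each measured member of the 22 gene lists with measured members, with decitabine minus untreated in log2 units on the horizontal axis and the lists, with their numbers of measured members, on the vertical axis. Each point is a gene, red where the adjusted p is below 0.05 and grey otherwise, and a black bar marks the list median, which runs from -1.79 for the ATF4 and unfolded protein list to 1.34 for the replication list.

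Markers of other cell types did not differ from the other genes as lists. Camera adjusted p-values were 0.943 for leukocyte (12 measured, median -0.13), 0.943 for erythroid (4, -0.03), 0.944 for neuronal (13, -0.05), 0.744 for hepatocyte (16, -0.07), 0.943 for muscle (7, 0.16), 0.648 for endothelial (12, 0.06) and 0.885 for melanocyte markers (8, -0.01). The neuronal median was below 0 while its mean of 0.14 and camera pointed upward, and the muscle mean was -0.02. Over all genes and over each list alone UCHL1, also in the tumour suppressor list, was the single neuronal marker that rose, and ERG, an ETS transcription factor, the single endothelial one (by 1.38). With the block 1 leukocyte marker rose and 1 fell, and 1 muscle marker fell.

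By camera, 9 of the 29 lists passed the threshold with the preset correlation, 1 of them with an estimated correlation, and 10 with the replicate block. By fry, 9 lists moved on balance in a single direction. These were ATF4 and unfolded protein (adjusted p = 2.72e-04), replication (0.00235), decitabine handling (0.00390), mitosis (0.0091), ribosomal proteins (0.0091), p53 targets (0.0379), imprinted genes (0.0379), cholesterol synthesis (0.0379) and germ line (0.0384). Fry gave 0.083 for cancer-testis antigens, 0.124 for interferon-stimulated genes and 0.260 for epithelial markers. With the replicate block 10 lists moved on balance in a single direction by fry. The block ended the fry call of mitosis (adjusted p = 0.0536), imprinted genes (0.0674), p53 targets (0.0878) and cholesterol synthesis (0.127). It brought past the threshold interferon-stimulated genes (0.00188), mesenchymal markers (0.00712), methylation machinery (0.0175), cancer-testis antigens (0.0294) and neuronal markers (0.0492), and gave 0.0638 for epithelial markers. For changes in either direction 20 lists passed, and 25 with the block, which added MHC class I presentation (0.0217), protocadherins (0.0217), endogenous retroviral genes (0.0104), leukocyte markers (0.0228) and endothelial markers (0.00821).

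Genes on the X chromosome made up 22 of 296 genes that rose and could be placed (7.43%), against 547 of 14577 other genes (3.75%), an odds ratio of 2.06 (95% confidence interval 1.26 to 3.21, Fisher's exact p = 0.00307). Without the cancer-testis list, which is rich in X-linked genes, the odds ratio was 1.82 (1.07 to 2.93, Fisher's exact p = 0.0180). For genes that also changed at least 2-fold it was 2.13 (1.30 to 3.33, Fisher's exact p = 0.00257). For the genes that rose with the replicate block, the odds ratio was 1.26 (0.925 to 1.68, Fisher's exact p = 0.129).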

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

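Array features without a gene name here were outside the comparisons above, and some differed between the groups. In a limma fit over all 48226 features, 197 of the 32128 unnamed features were higher after decitabine and 93 were lower at an adjusted p under 0.05, all of the 197 by at least 2-fold, and 1865 had an unadjusted p under 0.05. The largest rises were those of features 17103263, from a mean of 3.39 to 9.49 on the log2 scale (change 6.10, SE 0.39), and 17122122 (5.52, SE 0.33). The largest falls were those of features 17125032 (-3.75, SE 0.30) and 16848219 (-3.67, SE 0.32). No explanation was tested for them. In the same fit 408 features were higher and 171 lower in all.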

How the results depend on the processing

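The settings that left out both arrays of replicate 1, combined the replicate block with quantile normalization or with estimated correlations, or applied the block to the X-chromosome share were chosen after the data were examined. Higher and lower genes numbered 299 and 152, with 432 at least 2-fold, against 551 and 387 with quantile normalization, 280 and 91 with median centring, 426 and 246 without the dimmest 25% of genes, 557 and 432 without the dimmest 50%, 300 and 153 with averaged features, 682 and 453 with the intensity trend, 828 and 575 (757 at least 2-fold) with array weights, and 245 and 143 without replicate 1. Quantile normalization called 447 of the 451 genes again, median centring 295, the trend 443, array weights all 451, and the fit without replicate 1 316. Leaving out single arrays gave 95 to 321 higher, 33 to 156 lower and 130 to 476 at least 2-fold, and called 130 to 377 of the 451 again; these fits have fewer samples. With the replicate block, 1159 rose, 800 fell and 702 changed at least 2-fold, and with quantile normalization added 1225, 1046 and 714. The share of higher genes ran from 53.9% to 76.4% against 66.3%, and the median change over all genes was -0.02, moving to 0.118 without untreated replicate 1 and -0.135 without decitabine replicate 1. Pairing changed the call of the ribosomal list (0.0339 with the block, 0.0292 with quantile normalization too), of DCK, PEG10, RPL10A, SDF2L1, FOXF2 and FJX1, and of the X-chromosome share (odds ratio 1.256). It changed the call of no other gene named in the text and of no other list by camera at the preset correlation, while the fry calls it changed are given with the fry results. The ribosomal list also passed with quantile normalization (0.0459), averaged features (0.0473) and the trend (0.0282), and ran from 0.00852 to 0.524 over single arrays left out. The mesenchymal list passed with median centring (0.0338) and without replicate 1 (0.0192). Without the dimmest 50% of genes the interferon (0.145), decitabine handling (0.0536) and epithelial (0.182) lists missed the threshold, and decitabine handling ran from 6.66e-04 to 0.0539 over single arrays left out. With estimated correlations, adjusted p-values were 0.505 for cancer-testis antigens, 0.463 for germ line and interferon, 0.278 for decitabine handling, 0.128 for replication, 0.320 for mitosis, 0.584 for epithelial markers and 0.438 for cholesterol. With estimated correlations and the block they were 0.434 for cancer-testis antigens, germ line, interferon and ATF4, 0.489 for decitabine handling, replication, mitosis and epithelial markers, and 0.656 for cholesterol. Some lists that passed under none of the settings by camera changed their camera direction, which can differ from the sign of the median. Innate sensing did so without decitabine replicate 3 (adjusted p = 0.934, in a range of 0.728 to 0.982 over all single arrays left out). It also did so without the dimmest 50% (0.851) and with the trend (0.976). Muscle markers did so with median centring (0.930), without the dimmest 25% (0.997) or 50% (0.868), with the trend (0.976) and with array weights (0.861), with a median still above 0. They also did so without untreated replicate 3 (0.556) or decitabine replicate 1 (0.792), with a median below 0. Leukocyte markers did so without the dimmest 50% (0.855). Melanocyte markers did so without the dimmest 25% (0.997), without untreated replicate 1 (0.903) and without decitabine replicate 2 (0.791). The adjusted p of melanocyte markers over all single arrays left out, in either direction, ran from 0.589 to 0.903. Neuronal markers changed direction with the block (0.937, or 0.944 with estimated correlations) and without untreated replicate 2 (0.877) or decitabine replicate 1 (0.792). Endothelial markers did so without untreated replicate 3 (0.942). Over all single arrays left out, in either direction, adjusted p-values ran from 0.705 to 0.942 for neuronal and 0.230 to 0.942 for endothelial markers. Erythroid and hepatocyte markers changed direction without both arrays of replicate 1 (0.883 each) and without untreated replicate 1 alone (0.793 and 0.705). Erythroid markers also did so without untreated replicate 2 (0.877). Their adjusted p-values over all single arrays left out, in either direction, ran from 0.385 to 0.989 for erythroid and 0.279 to 0.907 for hepatocyte markers. The change of DNMT3A ran from -0.042 to 0.233 over single arrays left out, below 0 without untreated replicate 3 or decitabine replicate 1. Of the 40 named genes past the threshold, 25 kept their call with any single array left out and 15 lost it in at least 1 such fit. Under the other 10 alternatives, 437 of 462 values of named genes kept direction and side of the threshold, 11 no longer passed, 14 newly passed and none changed direction. Those lost were IFI44 with quantile normalization (0.0603), IFI44 (0.12), TRIM25 (0.105), INPP5F (0.174), CDC25A (0.0983) and KRT5 (0.0511) with median centring, and IFI44 (0.0548), TRIM25 (0.0835), INPP5F (0.069), GDF15 (0.0548) and BCL2L11 (0.0878) without replicate 1. Those gained outside the block were RPL10A with quantile normalization (0.0269), the trend (0.00256) and array weights (0.0134) and without the dimmest 25% (0.046) or 50% (0.0165), and PEG10 with the trend (0.012) and array weights (0.0401) and without the dimmest 50% (0.0406). Apart from the smaller number of samples or genes in some fits, the cause was not tested. No measure of signal over background was used, so how far dim features limit the values is not known beyond the fits without the dimmest genes.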

Other observations

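The gene lists in this part that were not fixed in advance, and the tests of oxygen limitation, culture density, phases of the cell cycle and the starting level of the germ-line list, were chosen only after the results were seen. Of 17 measured aminoacyl-tRNA synthetases of the cytosol, which load amino acids onto tRNAs, 7 fell and none rose (11 fell with the replicate block), with a median change of -0.58 on the log2 scale (-0.44, -0.70 and -0.68 in the pairs). MARS1 changed by -1.86 (SE 0.23), AARS1 by -1.63 (SE 0.25) and SARS1 by -1.63 (SE 0.21). The camera adjusted p was 4.93e-09 over 7 such lists, or 0.153 with an estimated correlation. Host genes of small nucleolar RNAs, whose introns carry guides of ribosomal RNA modification, gave 5 falls and no rise among 11, with a median of -0.99 (camera adjusted p = 1.03e-07, or 0.0526 with an estimated correlation). ZFAS1 changed by -2.05 (SE 0.21), SNHG8 by -1.35 and GAS5 by -1.03.

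Metallothioneins, small proteins that bind zinc and copper, gave 3 rises and no fall among 10 measured genes, with a median of 0.41 (camera adjusted p = 7.04e-05, or 0.153 with an estimated correlation). MT1L rose by 4.46 (SE 0.26), MT1F by 2.42 (SE 0.31) and MT1G by 2.08 (SE 0.41), from dim untreated means of 1.43, 2.66 and 1.40. These close copies may share signal on the array, which was not tested. The brightest members, MT2A and MT1X, with untreated means of 7.98 and 8.91, changed by 0.22 and 0.08 and did not pass. The 3 chaperone genes HSPA1A, HSPA1B and HSPA2 rose by 2.59 (SE 0.39), 1.61 (SE 0.29) and 1.60 (SE 0.30) among 13 heat shock genes (5 rose with the block), whose median was 0.52 (camera adjusted p = 2.75e-05, or 0.0601 with an estimated correlation). HSPA1A and HSPA1B are near-identical copies and cannot be read apart.

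The fall of the ATF4 and unfolded protein list (median -1.79) was weighed against 4 explanations. A scaling effect at this intensity is argued against by the list's place at percentile 0 of 10000 lists matched on mean expression, 99% of which lay between -0.29 and 0.35. For a fall of the whole unfolded protein response, 9 of 26 genes of an endoplasmic reticulum list were measured. Of these, SEC61A1, SEC61B, SPCS2, SPCS3 and SEL1L act in protein entry, signal peptide removal or degradation, and are not chaperones. The others were SDF2L1 (0.72), a member of the ATF4 list itself, CRELD2 (0.36), MANF (0.07) and HYOU1 (-0.27). The median of the 9 was 0.12, with a lower 95% bootstrap limit of -0.42. These 9 genes as a set argue against a fall as large as -1.79, but not against a smaller one. They cannot speak for the chaperones of that list that were not measured, and ERN1 and XBP1 of the unfolded protein response were lower. Of 39 hypoxia and glycolysis genes 25 were measured, with a median of 0.04 (0.06, 0 and 0.02 in the pairs) and a lower limit of -0.133. As a set these 25 argue against oxygen limitation in the untreated cultures. Yet the largest changes among them, DDIT4 (-3.28) and VEGFA (-2.02), went the way it predicts, while LOX rose by 1.22. The bootstrap limits given here resample genes, so they show the spread among listed genes and not between arrays. Denser untreated cultures, which could exhaust amino acids sooner, stay open: 13 YAP and TAZ targets, which this explanation predicts to rise, had a median of -0.30 (-0.44, -0.26 and -0.30 in the pairs, 95% bootstrap limits of -0.47 and 0.14) and a camera p of 0.362 with direction down. ANKRD1, CCN2 and THBS1 were higher and AXL lower, and with the block FOXF2 and FJX1 were lower too. A response to decitabine itself, with less demand on amino acid supply, may lie behind the fall of the ATF4 targets and tRNA synthetases that passed, and remains a hypothesis because no cell number or amino acid measurement was analysed here.

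The rise of the replication list (median 1.34, 18 of 29 genes higher) stood at percentile 100 of 10000 lists matched on mean expression, 99% of which lay between -0.26 and 0.27, which argues against scaling at this intensity. More cycling cells of every phase alike would raise replication and mitosis genes by similar amounts. The changes of all measured replication genes, past the threshold or not, were larger, by a median of 0.903 over the mitosis gene nearest in mean expression. The medians of 29 and 48 genes differed by 0.972 (permutation p = 1e-05, the smallest that 100000 resamples can give, and genes are not independent replicates). A candidate explanation is that more cells were at the entry into or within S phase after 72 h of the drug, but no cell-cycle measurement was analysed here.

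The rise of germ-line genes was weighed against noise of dim features, since many of these genes started near the bottom of the scale. Noise at the starting level of the list is argued against by 10000 lists matched on the untreated mean, which held at most 5 higher genes where the list held 14 (permutation p = 1e-04, the smallest these lists can give). Over all genes, 142 of 299 that rose (47.5%) were below the overall median of 3.64 in untreated cells, close to the 51.6% of all genes (7681 of 14884), and 19 of 152 that fell (12.5%) were below it in decitabine-treated cells (Fisher's exact p = 2.32e-14 for higher against lower genes). Among genes that changed at least 4-fold these shares were 75 of 98 (76.5%) and 4 of 21 (19%), so large rises started dim more often than genes in general, and how far background sets their size was not measured. Release of methylated promoters by the drug may account for the rise of the germ-line members that passed, as a hypothesis, since no methylation was measured in these data and 28 of the 42 members did not pass.

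The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the single split (1 of 10) with as many genes past the threshold (451, against at most 0 in the other splits), as many changed at least 2-fold (432 against 0) and as many lists past the threshold (9 against 7). At an unadjusted p under 0.05, the real split gave 2072 genes and the others 13 to 2014, the highest being the split with untreated replicates 1 and 2 and decitabine replicate 1 on a side. Of the 4 splits that part all 3 same-numbered pairs, the real one called 1959 genes with the replicate block and the others 0, with 13 to 50 genes at an unadjusted p under 0.05 without the block.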
